A study of Mus musculus with 6 samples.

How the data were processed

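Total RNA from sorted mouse embryo cells was measured on 6 Affymetrix arrays, 3 from wild-type and 3 from mutant embryos at embryonic day 9. Per the labels' protocols, the RNA was extracted with Trizol, amplified with a whole-transcript kit for very small inputs (WT-Ovation Pico), fragmented, labelled with biotin and hybridised. The cells carried a yellow fluorescent reporter switched on by Cre recombinase under the control of Isl1, and were isolated by fluorescence-activated sorting. Per the labels, the mutant embryos also carried a Ctnnb1 allele (the gene of β-catenin) whose exon 3 is flanked by loxP sites, so that Cre yields a stabilised protein. The series' design text speaks of independent experiments, and the labels do not say how many embryos went into each sample, so p-values measure the spread between these samples.

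The deposited values are on a log2 scale, 1 per probe set and array, for 45101 probe sets. The background correction, summarisation and normalization the authors used are not given in the sources used here. The log2 base was read from the values, which ran from 1.89 to 15.07, and the array medians lay between 6.47 and 6.50. The sorted values of the 6 arrays were nearly the same (largest SD at a rank 0.07), so the arrays appear already aligned to each other, and they were used without further scaling. If the authors aligned the distributions, a shift of most genes in one direction would have been removed before deposit. Amplification from very small amounts of RNA adds noise that no later step can take out.

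Probe sets were named through GEO's platform annotation, with symbols updated by gene identifier from a RefSeq gene table, which matched 34741 of the 34945 probe sets that name a single gene. A further 932 probe sets name several genes, 9160 are unnamed here and 64 are controls; these were left out of the gene-level test. Of 18193 genes, 9010 have several probe sets, and the one with the highest mean over all 6 arrays stood for the gene. No dim gene was removed. The 95th percentile of the means of 27 bacterial control probe sets, 4.85, served as a rough background level, and 4067 genes had a mean at or below it. No coordinates are given, since no genome build is named in the sources used here. The number of arrays limits the precision.

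Mutant and wild-type arrays were compared per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, 4 residual and 3.45 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All adjusted p-values of genes come from this fit. Differences are mutant minus wild type on the log2 scale, with moderated standard errors (SE). A single gene tested alone by exact permutation of 3 against 3 arrays cannot give a p below 0.1. A set of 25 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, with the correlation estimated per list as an alternative, and with fry beside it. For each list, members were also counted after adjustment over the list alone. The lists cover canonical Wnt targets, Wnt ligands and modulators, second heart field, cardiomyocyte, Notch, BMP and TGF-β, FGF, Hedgehog, retinoic acid and Hox, paraxial mesoderm, cell cycle, p53, endothelium, erythroid cells, macrophages, smooth muscle, gut endoderm, neural crest, neurons, surface ectoderm, matrix, immediate early and heat shock, glycolysis and hypoxia, oxidative phosphorylation and sex-linked genes. Members not measured under a single-gene probe set were not analysed here.

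The genes named are, by a rule fixed before the data were examined, the 12 in each direction with the largest change among called genes whose groups do not overlap (filled by the smallest p where fewer pass, as the text states), a panel of 25 genes, and the 3 members of each list with the smallest p. Members that passed over their list alone, the endothelial markers away from their list's median, members against their list's direction, and sex-linked, visceral endoderm and stress genes with uneven arrays, were named after their values were seen. The lists, the design and the alternatives were also fixed before the data were examined, except 6 further lists, the leaving out of each array for those lists, and the fit with a Y-linked covariate. The alternatives were replicate number as a block, quantile normalization, centring each array on its median, leaving out the 40% of genes with the lowest means, other ways of choosing probe sets, a trended robust prior, array weights, a log2 change of at least 1, a threshold of 0.01, and leaving out each array. A pseudocount was not needed, as the values were already log2.

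The fit was tested on simulated data: in 20 simulations of the comparison over 18193 genes with 200 changed genes, 75.5% of the changes of 1 and 99.2% of the changes of 2 on the log2 scale were recovered, with 10.45 false calls on average. The simulated noise was normal and independent, with each gene's moderated variance, and held no uneven arrays. These shares therefore do not give the recovery on the real arrays, and few calls there do not mean few changes. A list of 25 genes shifted by 0.5 was called in 20 simulations and an unshifted one in 0; those simulated genes were independent of each other, which genes of a list on real arrays are not. Figures were drawn with matplotlib 3.10.9.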

Results

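Cells of the Isl1 lineage, which at embryonic day 9 include the precursors of much of the heart, were profiled on 6 arrays: 3 of wild-type cells and 3 of mutant cells in which Cre recombination yields stabilised β-catenin, the transcriptional effector of canonical Wnt signalling. The series asks how a pathway of Notch1, β-catenin and Isl1 bears on the fate of cardiac progenitors, and the single comparison is mutant against wild type. Arrays correlated across genes at 0.986 to 0.989 within wild type, 0.985 to 0.987 within mutant and 0.979 to 0.987 between the groups. The first principal component held 36.4% of the variance and placed the wild-type arrays at −21.5, −20.5 and −21.6 and the mutant arrays at 1.21, 33.0 and 29.4, so that mutant replicate 1 lay between the groups. Sex-linked transcripts were uneven. The Y-linked gene Kdm5d read 9.84, 2.82 and 3.52 on wild-type arrays 1, 2 and 3 and 8.67, 9.92 and 9.08 on the mutant arrays, and Xist, expressed from the inactive X chromosome, read 5.46, 12.63 and 12.79 against 12.13, 7.54 and 12.44.

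Ctnnb1 itself read 12.98 ± 0.03 in wild type and 12.97 ± 0.04 in mutant cells (log2, mean ± SD, n = 3), a difference of −0.00. The array's probe sets are not known here to cover the deleted exon 3, so this level does not check the genotype. Isl1, the transcription factor whose locus drives the Cre, read 9.46 ± 0.28 in wild type and 8.27 ± 0.68 in mutant cells, a difference of −1.18 with SE 0.33 that did not pass (adjusted p = 0.269); a separate Isl1 probe set gave −1.21. The values of the 3 mutant arrays all lay below those of the wild-type arrays.

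Canonical Wnt targets stood higher in the mutant cells. Of 27 measured, 23 had higher values. With adjustment over all genes 1 rose, and 10 rose adjusted over the list alone, none fell, and 17 did not pass. Apcdd1, a membrane inhibitor of Wnt signalling, rose by 1.82 (SE 0.16), which is 3.52-fold, and passed over all genes (adjusted p = 0.0371). Those that passed only over the list alone were Sp5 at 1.23, Dkk1, a secreted Wnt antagonist, at 1.31, Wif1 (at 2.57 and 4.41 in the groups, below the background level) at 1.83, Notum at 1.19, Msx2 at 0.83, Axin2, a feedback inhibitor, at 0.74, Lgr5 at 0.64, Rnf43 at 0.56 and Tnfrsf19 at 0.50. Other target genes did not pass, with Nkd1 at 0.61 and Lef1 at 0.41. The list's median was 0.56 and camera called it up (adjusted p = 2.66e-11), but not with an estimated correlation (adjusted p = 0.238). Among 36 Wnt ligands, receptors and modulators, Dkk3 (0.87, with probe sets from 0.265 to 0.867) and Wnt1 (1.02) rose adjusted over the list alone, and 34 did not pass, Fzd1 (0.41) among them. The list was not called (median 0.04, adjusted p = 0.320).

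**Figure D1:**
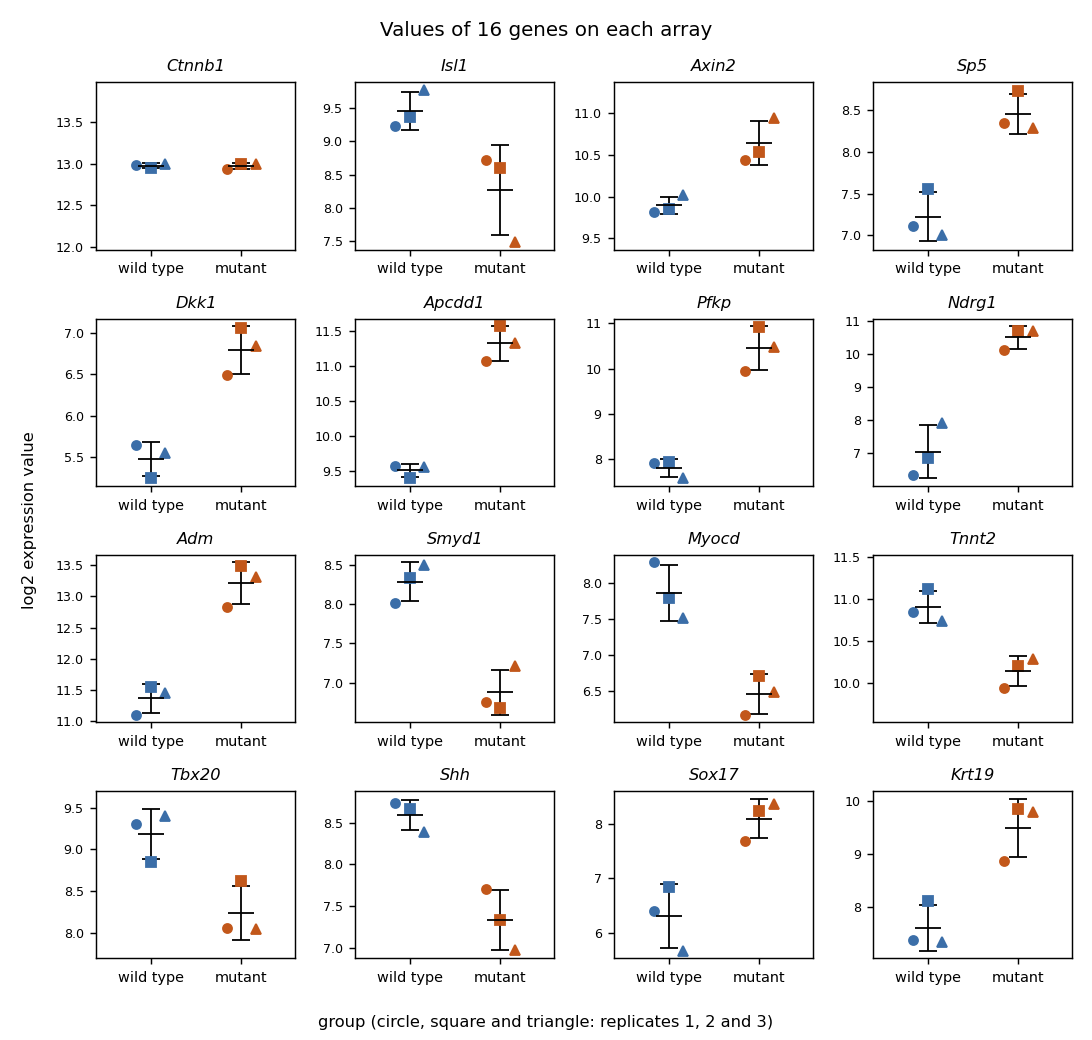
Log2 expression values of 16 genes on the 3 wild-type (blue) and 3 mutant (orange) arrays, with symbols for replicate numbers; horizontal bars give the mean and SD of each group, and vertical scales differ and do not start at 0. Ctnnb1 reads 12.98 and 12.97 in the groups, while Apcdd1, Pfkp, Ndrg1 and Adm, which passed over all genes, stand higher on each mutant array than on any wild-type array.

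Over all 18193 genes, limma called 12 genes higher in mutant cells and 0 lower. Among the 12, Pfkp, a phosphofructokinase of glycolysis, rose by 2.65 (SE 0.25, adjusted p = 0.0371), Pygl, a glycogen phosphorylase, by 1.88, and the cAMP phosphodiesterases Pde4b and Pde8a by 1.94 and 1.14. The secreted proteins Stc2 (2.63), Adm (adrenomedullin, 1.84), Igfbp3 (1.61) and Esm1 (2.89) also rose, as did Ndrg1 (3.46, SE 0.38, adjusted p = 0.0489), a gene known to be induced by low oxygen, the potassium channel subunit Kcne3 (3.46) and Fmo1 (1.13). Wild-type means of Kcne3, Esm1 and Fmo1 lay at or below the background level, and probe sets disagreed for Pde4b (−0.15 to 2.22), Apcdd1 (0.35 to 2.51), Ndrg1 (1.25 to 3.46) and Stc2 (1.27 to 2.63). All 12 genes were higher on each mutant array than on each wild-type array. Groups did not overlap for 3241 genes (17.8%, against 10% by chance), of which 1571 were higher and 1670 lower. At an unadjusted p under 0.05 there were 1230 higher and 880 lower genes, and log2 changes of at least 1 in size were seen in 197 higher and 66 lower genes. The number of calls rested on single arrays. It was 4 higher genes without wild-type replicate 1 (Kcne3 of the 12, Kdm5d and Eif2s3y, which are Y-linked, and an unnamed locus), 0 without wild-type replicate 2, 2 without wild-type replicate 3 (Kcne3 and Ndrg1) and 0 without mutant replicate 2 or 3. Without mutant replicate 1 it was 81 higher genes, all 12 among them, and 11 lower genes. With the Y-linked signal as a covariate, added after the uneven sex-linked values were seen, Kcne3 alone was called. Over the 18 alternatives, this one among them, none of the 12 genes changed sign, though Esm1 and Fmo1 were tested in 17. Some of the alternatives cannot change a sign, as stated below. The smallest log2 changes of the 12 genes there ran from 0.89 (Pde4b) to 3.07 (Kcne3).

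No gene passed in the downward direction; the smallest adjusted p was 0.0881. The 12 lower genes with the smallest p and groups that did not overlap included Smyd1, a muscle histone methyltransferase, at −1.40, which had the smallest p, and Myocd (myocardin, a coactivator of heart and smooth muscle genes) at −1.40. Shh, the signal secreted by pharyngeal endoderm, stood at −1.26, Rhbdl3 at −1.49, the haematopoietic transcription factors Myb and Gfi1 at −1.19 and −0.99, and Chga at −0.92. The others were Cox7c (−0.84), Pole3 (−0.72), Mgat5b (−0.69), Htr2c (−0.65, at or below background in both groups) and Cd37 (−0.64). Mutant means of Gfi1 and Mgat5b lay below background. Probe sets differed in sign for Smyd1 (−1.40 to 0.03), Htr2c (−0.65 to 0.08) and Cd37 (−0.64 to 0.01). They differed in size for Myocd (−1.40 to −0.19), Shh (−1.26 to −0.17), Pole3 (−0.72 to −0.19), Rhbdl3 (−1.49 to −0.59) and Myb (−1.40 to −0.74).

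Among the lists fixed beforehand, that of glycolysis and the response to low oxygen had the highest median apart from the 4 sex-linked genes. All 19 measured members had higher values. Pfkp, Adm and Ndrg1 rose over all genes, and 16 rose adjusted over the list alone. Among these were Bnip3, a mitophagy receptor, at 1.78, Egln3, an oxygen-sensing prolyl hydroxylase, at 1.72, Ankrd37 at 1.69, the glucose transporters Slc2a3 and Slc2a1 at 1.32 and 0.47, Pdk1 at 0.97, Hk2 at 0.91, Pfkl at 0.82, Hk1 at 0.70, Vegfa at 0.56, Tpi1 at 0.52, Aldoa at 0.49 and Pgk1 at 0.41. The basic helix-loop-helix repressor Bhlhe40, in the panel but not in this list, stood at 2.70 (SE 0.31) and just missed the threshold over all genes (adjusted p = 0.0523). The list mean, relative to the wild-type mean, was 0.75, 1.31 and 1.29 on the mutant arrays and between −0.09 and 0.05 on the wild-type arrays. Camera called the list up (median 0.82, adjusted p = 6.03e-19), but not with an estimated correlation, which was 0.53 (adjusted p = 0.238). Y-linked transcripts, on average, and the immediate early and heat shock list stood higher on the mutant arrays too. Oxidative phosphorylation genes did not differ as a list (23 measured, median −0.04, adjusted p = 0.402), with Cycs at −0.53, Uqcrh at 0.29 and Atp5o at −0.20.

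Of 34 cardiomyocyte differentiation genes, 3 fell adjusted over the list alone and none over all genes, none rose, and 31 did not pass. Values were lower for 22 members and higher for 12, among them the natriuretic peptide Nppa at 1.16 (adjusted p = 0.0514 over the list alone) and the calcium channel subunit Cacna1c at 0.57. The 3 that fell were Smyd1 (adjusted p = 0.00425 over the list alone), Myocd (0.00643) and Tnnt2, cardiac troponin T, which fell by 0.76 (0.0167). Probe sets of Tnnt2 ran from −0.78 to −0.11. The list was called down by camera (median −0.17, adjusted p = 0.0332) but not with an estimated correlation (adjusted p = 0.561), without wild-type replicate 2 (0.384), without mutant replicate 1 (0.238), with ranks (0.0739) or with the Y-linked covariate (0.521). Its median was −0.0588 without wild-type replicate 2 and −0.12 without mutant replicate 1. The cardiomyocyte mean, relative to the wild-type mean, was −0.27, −0.19 and −0.12 on mutant arrays 1, 2 and 3, and −0.13 on wild-type array 1. Of 25 second heart field progenitor genes none passed over the list alone, and the list was not called (median −0.04, adjusted p = 0.239), though it was called down with every probe set tested (median −0.13, adjusted p = 0.0448). The second heart field median was −0.18 without wild-type replicate 1, and −0.0120, −0.17 and −0.0877 without mutant replicates 1, 2 and 3. Relative to the wild-type mean, the list's mean was −0.44 on mutant array 1 and −0.05 and −0.08 on the other two. Its members went both ways: the transcription factors Osr1 (−1.05), Tbx20 (−0.94), Gata4 (−0.87), Tbx5 (−0.71), Nkx2-5 (−0.46) and Hand2 (−0.29) stood lower, and Foxc2 (0.61), Fgf8 (0.47) and Tbx1 (0.41) higher, while Mef2c (0.03) and Fgf10 (0.01) were near 0. Nkx2-5 lay at or below background in both groups, at 4.82 and 4.36, so its difference is not a measured fall. None of these single differences passed.

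**Figure D2:**
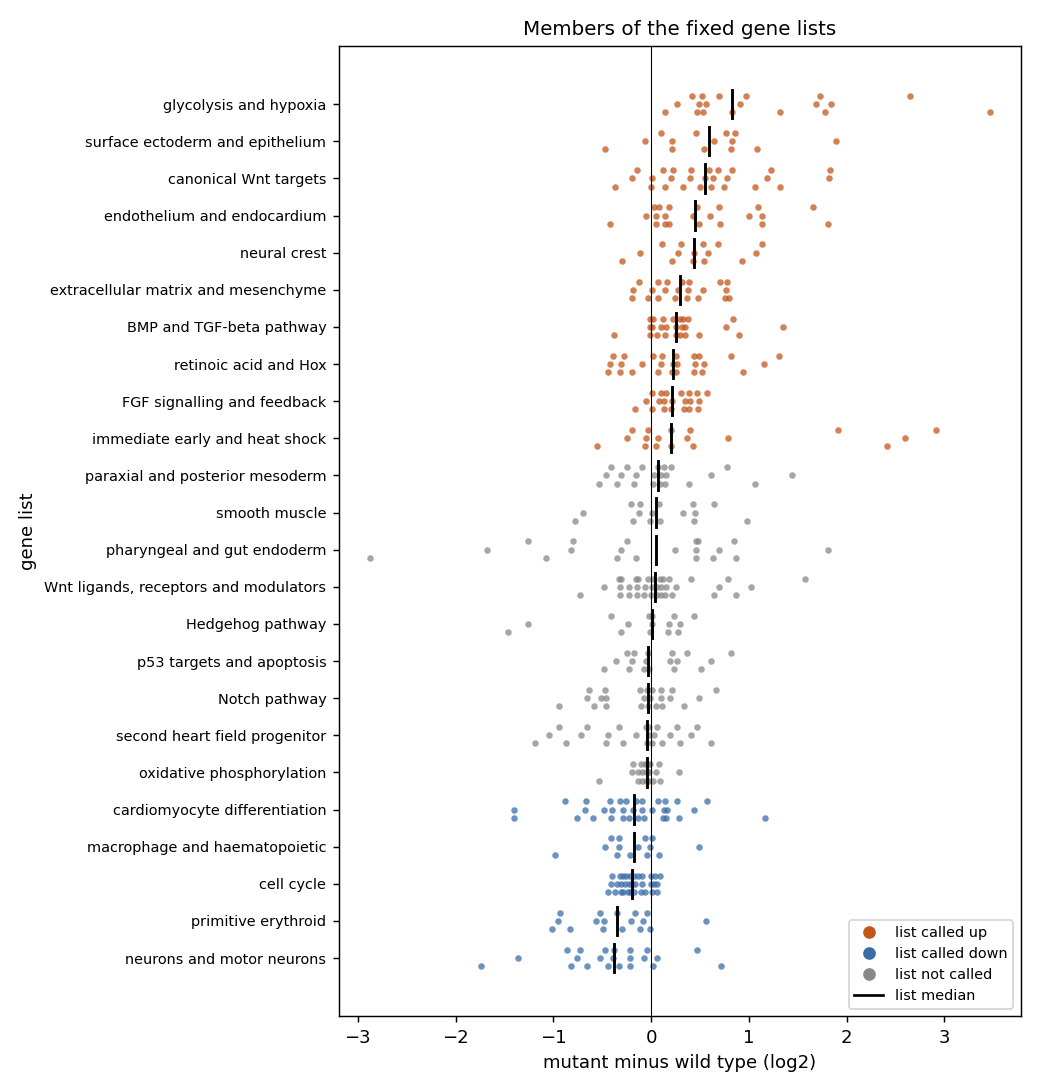
Mutant minus wild-type log2 difference of each measured member of 24 fixed gene lists (the sex-linked list is left out), each point a gene and each black bar the list median; colour shows camera's call at the preset correlation. Medians run from −0.38 for neurons to 0.82 for glycolysis and hypoxia, whose 19 members all lie above 0.

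Among other signalling lists, FGF signalling and feedback was called up (21 measured, 19 with higher values, median 0.21, adjusted p = 0.000248), with the feedback inhibitors Spry1 at 0.49 and Spry2 at 0.48 and with Fgf15 at 0.57. No member passed over the list alone, and the adjusted p with an estimated correlation was 0.238. The BMP and TGF-β list was called up (26 measured, median 0.25, adjusted p = 0.00132) with no member passing, Bmp2 at 1.35, Fst at 0.90, Bmp4 at 0.84 and Id2 at 0.30. Its adjusted p was 0.359 with an estimated correlation and 0.0893 without the dimmest 40% of genes, and its median 0.17 without wild-type replicate 2 and 0.16 without mutant replicate 2. The mean of the BMP and TGF-β genes was lower on mutant array 1 (0.08, relative to the wild-type mean) than on wild-type array 3 (0.15). Retinoic acid and Hox genes were called up (27 measured, median 0.22, adjusted p = 0.0416) with Hoxa9 at 0.54, Rdh10 at 0.52 and Cyp26a1 at 0.49 and no member passing. The call was lost with an estimated correlation (adjusted p = 0.583), with quantile normalization (0.0554), with the most variable probe set (0.0795), without the dimmest 40% of genes (0.272), and without wild-type replicate 1 (0.435), mutant replicate 2 (0.152) or mutant replicate 3 (0.487). The retinoic acid and Hox median was 0.12 and 0.34 without wild-type replicates 1 and 3, and 0.36, 0.0263 and 0.10 without mutant replicates 1, 2 and 3. The Notch list was not called (24 measured, median −0.03, adjusted p = 0.569), with Notch1 at −0.04, its target Hes1 at 0.19, Hes5 at −0.63, Dll3 at −0.58 and Notch4 at 0.49. Probe sets of Notch4 ran from −0.08 to 0.72. Of 15 Hedgehog genes Shh fell adjusted over the list alone, Cdon stood at 0.44 and Boc at −0.41, and the list was not called (median 0.01, mean −0.14, camera down, adjusted p = 0.786). Paraxial and posterior mesoderm genes were not called (23 measured, median 0.07, adjusted p = 0.348), with Evx1 at 1.45 and Cdx1 at 1.06.

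Markers of several other cell types stood higher in the mutant cells. Of 22 endothelial and endocardial genes 7 rose adjusted over the list alone, none over all genes: Sox17 (1.80), Flt1 (1.66, with probe sets from 0.32 to 2.10), Sox18 (1.14), Pecam1 (1.14), Robo4 (1.09, wild-type mean below background), Erg (1.01) and Esam (0.69). The other 15 did not pass, among them Eng at 0.05, Gpr182 at −0.05 and Nfatc1 at −0.42. The list was called up (median 0.45, adjusted p = 8.91e-07; 0.359 with an estimated correlation), with a median of 0.27 without wild-type replicate 3. Of 15 neural crest genes 5 rose adjusted over the list alone, namely Snai2 (1.14), Sox10 (1.07), Tfap2a (0.93), Tfap2b (0.58) and Ets1 (0.44). The list was called up (median 0.44, adjusted p = 1.32e-05; 0.238 with an estimated correlation), with a median of 0.28 without wild-type replicate 3. Of 14 surface ectoderm genes 4 rose adjusted over the list alone, namely the keratin Krt19 (1.89), Grhl3 (1.08, wild-type mean below background), Tfap2c (0.83) and Cdh3 (0.54, with probe sets from −0.02 to 0.54). The list was called up (median 0.59, adjusted p = 0.000248; 0.359 with an estimated correlation), with a median of 0.23 without mutant replicate 3. The mean of the surface ectoderm genes was lower on mutant array 1 (0.19, relative to the wild-type mean) than on wild-type array 2 (0.27). Extracellular matrix genes were called up (22 measured, median 0.30, adjusted p = 0.00132, or 0.359 with an estimated correlation) with no member passing. Fbln2 stood at 0.79 (probe sets from 0.06 to 0.79), Sparc at 0.71 and Fn1 at 0.38. Relative to the wild-type mean, the matrix mean was 0.08, 0.48 and 0.35 on mutant arrays 1, 2 and 3, and 0.31 on wild-type array 3.

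Smooth muscle genes were not called as a list (16 measured, median 0.05, adjusted p = 0.348): Tagln (0.98) and Cnn2 (0.65) rose and Synpo2 (−0.78) fell adjusted over the list alone. Pharyngeal and gut endoderm genes were not called (20 measured, adjusted p = 0.894). Over the list alone, Sox17, which endothelium also expresses, rose and Shh fell, while Foxa1 stood at −1.07. This list's median (0.05) was above 0, its mean (−0.13) below 0, and camera and fry gave opposite directions. Of its members Ttr and Afp, secreted by visceral endoderm, differed between arrays of one group: Afp read 4.08, 11.51 and 11.52 on the wild-type arrays and 2.60, 9.46 and 10.00 on the mutant arrays.

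**Figure D3:**
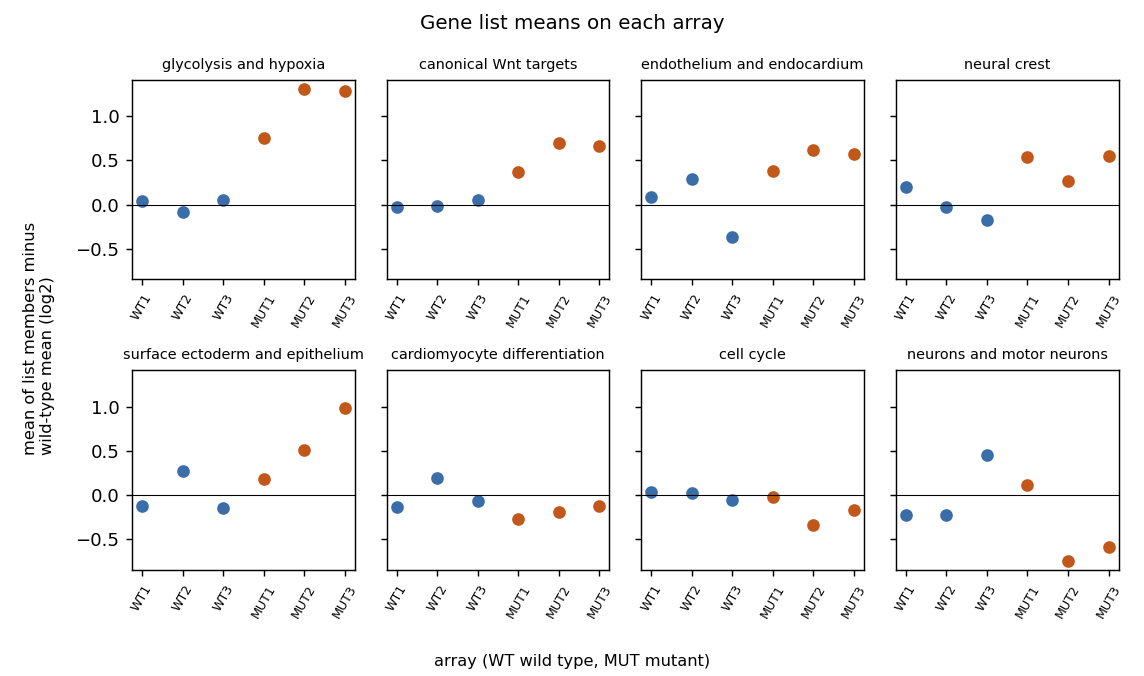
Mean of list members on each array minus the mean of the wild-type arrays (log2) for 8 gene lists; blue points are the 3 wild-type arrays and orange points the 3 mutant arrays. For glycolysis and hypoxia the mutant arrays read 0.75, 1.31 and 1.29, and for neurons mutant replicate 1 reads 0.12 against −0.75 and −0.59 on the other two.

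Markers of neurons, blood cells and cycling cells stood lower on average, with no member passing in any of these lists, but mutant arrays differed. Relative to the wild-type mean, the neuronal mean was 0.12, −0.75 and −0.59 on mutant arrays 1, 2 and 3. The mean was −0.48, −0.91 and 0.25 for primitive erythroid genes and 0.05, −0.43 and −0.22 for macrophage genes. For cell cycle genes it was −0.02, −0.34 and −0.17. The lowest wild-type array read −0.23, −0.37, −0.16 and −0.06 for these lists in turn. Neuronal genes were called down (22 measured, median −0.38, adjusted p = 0.0102), with Neurod4 at −1.74 (probe sets from −1.74 to −0.19), Elavl3 at −1.37 (probe sets from −1.37 to −0.08) and Sox2 at −0.52. The call was lost with an estimated correlation (adjusted p = 0.561), without wild-type replicate 3 (0.381) or mutant replicate 2 (0.120) and with the Y-linked covariate (0.483), and the median was −0.16 without wild-type replicate 3. Primitive erythroid genes were called down (17 measured, median −0.35, adjusted p = 0.0185), with Ank1 at −0.95 (probe sets from −0.95 to −0.06), Tal1 at −0.94 and Lmo2 at 0.56. This call was lost with an estimated correlation (adjusted p = 0.599), with array weights (0.213) and without wild-type replicate 1 (0.319), mutant replicate 1 (0.164) or mutant replicate 2 (0.481). The erythroid median was −0.18 and −0.64 without wild-type replicates 1 and 3, and −0.14 and −0.75 without mutant replicates 2 and 3. Macrophage genes were called down (14 measured, median −0.18, adjusted p = 0.0416), with Coro1a at −0.47, Cx3cr1 at −0.35 and Fcer1g at −0.33. That call was lost with an estimated correlation (adjusted p = 0.359), without the dimmest 40% of genes (0.242), with the most variable probe set (0.114), with the Y-linked covariate (0.401), and without wild-type replicate 2 (0.0927) or 3 (0.100) or mutant replicate 2 (0.106) or 3 (0.0989). The macrophage median was −0.28 without mutant replicate 1 and −0.12 without mutant replicate 3. Cell cycle genes were called down (33 measured, 27 with lower values, median −0.19, adjusted p = 0.00132), with Ccne2 at −0.41, Rrm2 at −0.40 and Kif11 at −0.37. The adjusted p was 0.561 with an estimated correlation and 0.110 without mutant replicate 2, where the median was −0.11. The p53 and apoptosis list was not called (18 measured, median −0.03, mean 0.07, adjusted p = 0.390), with Bcl2 at 0.61, Ccng1 at 0.36 and Bak1 at −0.48. Probe sets differed in sign for Bcl2 (−0.24 to 0.61) and Ccng1 (−0.09 to 0.36).

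Of 18 immediate early and heat shock genes Ier3 rose by 2.91 adjusted over the list alone, Hspa1b stood at 1.91, Hspa1a at 2.42, Egr1 at 0.78 and Klf6 at 0.37. Values were higher for 12 members and lower for 6, among them Jun at −0.25 and Fosb at −0.55 (below background in both groups), while Fos stood at 0.05. The list was called up (median 0.20, adjusted p = 0.0102; 0.359 with an estimated correlation). Its median was 0.31 without wild-type replicate 2, and 0.35, 0.13 and 0.0655 without mutant replicates 1, 2 and 3. Hspa1a read 4.92, 7.02 and 8.89 on mutant arrays 1, 2 and 3 and 3.76 to 5.01 on the wild-type arrays, whose mean was below background. Egr2 was uneven as well, at 9.23, 4.43 and 3.91 on the wild-type and 9.62, 8.03 and 7.70 on the mutant arrays. The 4 measured sex-linked genes were called up as a list (median 2.93, adjusted p = 0.0288), with Kdm5d at 3.83, Eif2s3y at 3.59 and Uty at 2.28 (wild-type mean below background) and none passing. Its call was lost with an estimated correlation (adjusted p = 0.359), without the dimmest 40% of genes (0.166), and without wild-type replicate 2 (0.0687) or 3 (0.0756) or mutant replicate 1 (0.0947) or 3 (0.0530). The sex-linked median was 4.68 without wild-type replicate 1.

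In all, camera at the preset correlation called 16 of the 25 lists, 11 up and 5 down, and with an estimated correlation it called 0, with 4 at an unadjusted p under 0.05. Fry's directional test called 3 lists, canonical Wnt targets, FGF signalling and glycolysis and hypoxia (adjusted p = 0.0478 for each), and its mixed test 12.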

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

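All tests in this part were chosen after the results they bear on were seen. Glycolysis and hypoxia genes stood higher on all 3 mutant arrays. More male cells in the mutant samples would leave no difference once the Y-linked signal is in the fit. The list's mean difference was 1.05 with it (95% interval 0.17 to 1.92) and 1.12 without it (0.60 to 1.64), which argues against sex as the whole cause. That argument leans on wild-type replicate 1, the only wild-type array with a high Y-linked signal. Group and Y-linked signal correlated at r = 0.64. Harsher dissociation of mutant tissue would raise immediate early and heat shock genes as much. Their median was 0.20 (bootstrap 95% interval −0.04 to 0.61, and 0.0655 to 0.35 when single arrays were left out). For glycolysis and hypoxia it was 0.82 (0.52 to 1.69), and the explanation stays open because these intervals overlap. The bootstraps resampled the genes of a list and not the arrays, so the intervals hold no spread between samples and take genes as independent. The criterion was changed after its outcome was seen: as first written it asked only whether the upper bound of 0.61 lay below 0.82, which it does and which would have excluded dissociation, but that left out the spread of the glycolysis and hypoxia median. As a hypothesis, the genotype, through β-catenin itself or through a poorer oxygen supply of mutant embryos, may also account for the pattern, and these data hold no test that separates those.

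Mutant replicate 1 lay between the groups. Across genes it correlated more with wild-type replicate 1 (0.9872) than with mutant replicates 2 and 3 (0.9851 and 0.9860). Whether these arrays share an experiment was not tested. For the 81 genes higher and 11 lower in mutant replicates 2 and 3 against wild type, which were picked without replicate 1, that array showed a median of 0.333 (bootstrap 95% interval over genes 0.29 to 0.39) and 0.40 (0.08 to 0.51) of the linear change. Genes picked for passing in replicates 2 and 3 tend to have their change there overstated. That lowers the fractions by an amount that was not estimated, so a fraction below 1 alone does not show a smaller change in replicate 1. An admixture of cells without the activated allele may give such overlapping fractions, but the interval for the 11 lower genes is wide and a weaker response of all cells may look alike. An admixture would keep the fraction of a single gene between 0 and 1. The log2 mean of a list whose members go both ways may leave that range even so. For the means of the 15 called lists other than the sex-linked one, the log2 fraction was below 0 for 3 (retinoic acid and Hox −0.52, neurons −0.17, macrophages −0.16). It was above 1 for 3 (cardiomyocyte 1.73, erythroid 1.47, neural crest 1.33). The spread of these fractions was not estimated, so admixture, first read as matching the values, is left open. Degraded RNA might set the array apart in the 3′ minus 5′ signal of the Gapdh controls, which was 1.35 there and 1.04 to 1.53 on the other 5 arrays. For the Actb controls it was 0.04 there and −0.02 to 0.15 on the others. Neither control set the array apart. How far they track degradation after whole-transcript amplification is not known here, so degraded RNA is left open.

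Endothelial markers were unequally higher. Were a larger share of endothelial cells the whole cause and each marker bright and specific to them, the markers would move alike, by about the list's median of 0.45. For 7 of 22 the 95% interval left that value out, 4 above it (Sox17, Flt1, Sox18 and Pecam1) and 3 below it (Eng, Gpr182 and Nfatc1), more than 5% of 22 would give (one-sided exact binomial p = 6.84e-05, with genes taken as independent, which they are not). This was first read as excluding cell share alone and is left open, because Gpr182 and Nfatc1 are among the dimmest 40% of genes and a marker that other sorted cells also express would move less. Under the criterion set afterwards, only markers whose 95% interval lay below 0 would argue against cell share, and there were 0. Flt1, among the 4 markers above the list's median, had probe sets from 0.32 to 2.10. As hypotheses, a change in cell share, which the Isl1-Cre sort would not remove, and a change of state within endothelial cells may each account for the pattern.

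For the 12 genes called higher, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many, and the highest other split gave 0. For the 16 lists called, 1 split gave as many and the highest other split gave 15, with wild-type replicates 1 and 3 and mutant replicate 1 against the rest. With 10 splits no share can fall below 0.1, so the splits cannot reach 0.05.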

How the results depend on the processing

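The Y-linked covariate was chosen after the data were seen, and the other settings before. The count of 12 genes higher in mutant cells became 6 with arrays centred on their medians, 1 with the mean of a gene's probe sets (Igfbp3), 1 with the most variable probe set (Egln3, not among the 12), 0 at an adjusted p under 0.01 and 1 with the Y-linked covariate (Kcne3), which leaves 1 degree of freedom fewer; with the other settings that keep all arrays and ignore the replicate number it was 8 (probe sets, of 6 genes) to 16. Leaving out each array gave 0 to 81 genes higher and 0 to 11 lower. The 12 genes of the main fit kept their sign under every alternative in which they were tested, the Y-linked covariate included. For Esm1 and Fmo1 these were 17 of the 18. The replicate block, the trended robust prior, the minimum log2 change and the stricter threshold leave log2 changes as they are. With every probe set tested, the same probe set was followed for each gene. These settings therefore do not test the sign. The smallest log2 changes of the 12 genes ran from 0.89 (Pde4b) to 3.07 (Kcne3). With the replicate number as a block 0 genes were called higher or lower, with fewer residual degrees of freedom. Deviations of same-numbered arrays from their group means correlated at 0.108, −0.075 and −0.016, and 1 of the 3 wild-type arrays correlated best with its own number. For replicates 2 and 3 these values show no pairing by number, but with 3 arrays per group they cannot exclude it. The arrays numbered 1 resembled each other. Across genes they correlated at 0.9872, above wild-type array 1 with wild-type arrays 2 and 3 (0.9860 and 0.9858). They also had the highest values, 28.4 and 15.2, on the second principal component, which held 20.3% of the variance. Whether a shared experiment accounts for this was not tested. The 16 lists became 9 at an adjusted p under 0.01 and 0 with an estimated correlation, which is larger than the preset for most lists. Glycolysis and hypoxia, canonical Wnt targets, FGF, BMP and TGF-β, neural crest, endothelium, surface ectoderm, matrix and immediate early and heat shock lists were called whichever array was left out. For BMP and TGF-β, surface ectoderm and matrix genes, the list mean was still lower on mutant array 1 than on a wild-type array.

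Of 174 genes followed over up to 18 alternatives, 158 never changed sign. The settings named above that cannot change a sign are counted among the 18. For the sign changes the cause was not tested. Fgf10 became −0.00154 with quantile normalization and −0.00500 with median centring. Ctnnb1 became 0.0594 with the mean of its probe sets, 0.0465 with the most variable one and 0.00368 with array weights. Fos became −0.000962 with array weights, Hif1a 0.23 with the mean of its probe sets and 1.28 with the most variable one, and Ccng1 −0.0872 with the most variable one. With the Y-linked covariate Afp became 2.02, Atp5o 0.0177, Egr2 −0.11, Eif2s3y −0.0358, Fgf10 −0.14, Mef2c −0.20, Notch1 0.20 and Uty −0.0139, and the medians of the Notch, p53 and oxidative phosphorylation lists 0.13, 0.12 and 0.0211. The Hedgehog median became −0.0106 with median centring, −0.0772 with probe set means, −0.18 with the most variable probe set, −0.10 with every probe set tested and −0.0211 with array weights. The p53 median became 0.19 without the dimmest 40% of genes, also as the list background alone, and 0.10 with probe set means. With every probe set tested the paraxial mesoderm median became −0.0288 and the gut endoderm median −0.22. Leaving out each array gave log2 differences of −0.0166 to 0.0192 for Ctnnb1, −0.12 to 0.14 for Fgf10, −0.22 to 0.10 for Notch1, −0.13 to 0.16 for Mef2c, −0.22 to 0.0910 for Gpr182, −0.0489 to 0.14 for Eng, −2.01 to 1.99 for Xist, −0.15 to 1.68 for Rbp4, −0.16 to 0.42 for Fos and −4.16 to 0.70 for Afp, and medians of −0.0662 to 0.10 for Hedgehog, −0.0688 to 0.11 for paraxial mesoderm, −0.0712 to 0.0425 for p53, −0.0158 to 0.15 for smooth muscle, −0.18 to 0.43 for gut endoderm and −0.12 to 0.0551 for Notch. Differences of genes near the background level of 4.85 understate or lose any change.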

Other observations

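The lists in this part, and the leaving out of single arrays for them, were chosen after the values were seen, so their counts describe the pattern and are not independent evidence. Genes linked to hypoxia-inducible factors, outside the glycolysis list, stood higher in the mutant cells. The list holds genes known to be induced by these factors and also Hif1a and Epas1, which encode such factors. Of 20 measured, 16 rose adjusted over the list alone, 1 of them (Stc2) over all genes. Among them were Bhlhe40 (2.70), the glycogen-targeting subunit Ppp1r3c (2.32), Rora (2.28), Vldlr (2.17), Ddit4, an inhibitor of mTORC1, (2.05), the collagen prolyl hydroxylases P4ha2 (1.97) and P4ha1 (1.17), the disulphide oxidase Ero1a (1.55), Ndufa4l2 (1.49), Pfkfb3 (1.36), Epas1 (1.30), Egln1 (1.10), Kdm3a (0.86), Fam162a (0.86) and Higd1a (0.67). Probe sets of Rora ran from −0.03 to 2.28 and those of Ppp1r3c from 0.92 to 2.32. The members with lower values were Pfkfb4 (−0.15) and Hif1a (−0.23, with probe sets from −0.23 to 1.28). Camera called the list up (median 1.33, adjusted p = 3.40e-19 over the 6 lists; adjusted p = 0.153 with an estimated correlation).

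Genes of the amino acid response, namely Atf4 and targets of this transcription factor, had higher values too for 13 of 14 measured. Adjusted over the list alone 6 rose, namely Chac1 (2.53, wild-type mean below background), Trib3 (1.75), Cth (0.83), Ddit3 (0.78, with probe sets from −0.09 to 0.78), the asparagine synthetase Asns (0.68) and Mthfd2 (0.49). The others did not pass, among them Psat1 (0.16), Atf4 itself (0.05) and Phgdh (−0.03). The list was called up (median 0.46, adjusted p = 1.14e-06, or 0.153 with an estimated correlation). Genes of the unfolded protein response were not called (12 measured, median −0.09, adjusted p = 0.387), although Herpud1 rose by 0.68 adjusted over the list alone. Cholesterol synthesis genes were called down (13 measured, median −0.48, adjusted p = 6.02e-05; 0.438 with an estimated correlation) with no member passing, Cyp51 at −0.60 and Lss at −0.59. The mean of these genes, relative to the wild-type mean, was −0.06, −0.92 and −0.40 on mutant arrays 1, 2 and 3 and −0.05, 0.21 and −0.15 on the wild-type arrays. Without mutant replicate 2 their median was −0.26 (adjusted p = 0.0128). Genes of visceral endoderm, most of which encode secreted proteins, were called down (14 measured, median −0.87, adjusted p = 0.0151, or 0.438 with an estimated correlation) with no member passing. Values were lower for 12, such as Ttr at −2.87 and Apom at −1.40. They were higher for 2, the endocytic receptor Cubn at 0.79 (the smallest p of the list, adjusted p = 0.0519 over the list alone) and Rbp4 at 0.85. Probe sets of Cubn ran from −0.03 to 0.79. The mean of the visceral endoderm genes, relative to the wild-type mean, was −1.15, 0.71 and 0.43 on wild-type arrays 1, 2 and 3 and −1.52, −0.61 and −0.16 on the mutant arrays. The call was lost without wild-type replicate 2 (median −0.39, adjusted p = 0.154) or mutant replicate 1 (−0.52, adjusted p = 0.250), and the median was −1.47 without wild-type replicate 1 and −0.57 without wild-type replicate 3. Interferon response genes were not called (9 measured, median −0.12, adjusted p = 0.363).

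Outside the gene-level test, 10092 probe sets that name no gene or several genes were compared with limma in the same way; 0 passed, with 874 at an unadjusted p under 0.05. Of 64 control probe sets 0 passed, with 4 at an unadjusted p under 0.05.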
